A study of Mus musculus with 12 samples.

How the data were processed

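Single cells from mouse brain were profiled in 12 libraries, 1 sham library of each sex at each age and 2 PDMCAO libraries of each sex at each age, 14 days after surgery. PDMCAO is the submitters' abbreviation for their stroke surgery. The labels state that mice were perfused, that a brain slice was dissociated with a commercial kit and that cells were captured with 10X Chromium. They record age and sex under tags meant for other things, so each library was placed by its title and these values together. The deposited files hold a raw unique molecular identifier (UMI) count per gene and cell barcode, for barcodes already called as cells, which the authors made with Cell Ranger 2.1.1 and the mm10 genome build per the submitters' processing notes. The header of female PDMCAO aged 2 instead names version 7.1.0, and that library lists 31053 genes against 27998 in the other 11. Whether intron reads were counted is not given in the sources used here. No normalization had been applied to the deposited counts, which were checked to be whole numbers with totals that differ between barcodes.

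The 27514 genes listed in all 12 libraries were used, of which 27403 (99.6%) were found in the annotation. At most 0.950% of barcodes were shared by 2 libraries. Of 32061 barcodes, 1008 were removed for fewer than 200 genes or over 20% mitochondrial counts. A further 754 were removed as doublets, those with the most simulated doublets among their neighbours, at a rate of 0.8% per 1000 barcodes of a library. Counts of the 30299 kept cells were scaled per cell and log-transformed, and 2000 variable genes without sex-linked and mitochondrial ones, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 were used (scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). A cluster was named after the cell type whose marker genes, fixed before the data were examined, were highest in it relative to the cluster where each is highest, if their median there reached 0.2. It stayed unnamed if markers of another, unrelated type reached 0.11, and 2 further rules, on detected markers and depth, set no cluster aside. These rules and limits, and the merging of related types, were chosen after the clusters were seen. A limit of 0.1 was considered first and 0.11 kept 1 cluster of 133 T and NK cells named, whose B and plasma cell markers were at 0.103. Names are therefore of cells like a type, not proof of it.

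Depth was 6242608 to 25186976 UMIs per library, and 1121750 (female sham aged 1) to 8593810 (female PDMCAO aged 2) UMIs in microglia. In a simulation, counts were drawn anew for each gene alone, from its mean and spread and the depth of each library, with changes added. It thus holds no library that shifts many genes at once, so its rates may not hold for the real counts. With 12 libraries, 81% of genes changed 4-fold and 28% of genes changed 2-fold were called in microglia for PDMCAO minus sham. For age in sham these were 39% and 3%. Without female PDMCAO aged 2 they were 93% and 80% for surgery and 74% and 35% for age in sham. In other cell types 64% to 87% of genes changed 4-fold were called with 12 libraries. Without female PDMCAO aged 2, 5.93% to 7.29% of the calls in microglia were of unchanged genes, and with all 12 libraries 2.65% to 4.55%. In the other types these were 11.3% (surgery) and 8.94% (age) in endothelial cells, 9.62% and 9.88% in astrocytes, and 8.73% and 3.41% in oligodendrocytes, where an adjusted p of 0.05 allows 5%.

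UMI counts were summed over the cells of each type in each library. They were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the robust quasi-likelihood F test, with TMM normalization, filterByExpr over the 4 age and surgery groups, and sex as an additive term, in microglia, endothelial cells, astrocytes and oligodendrocytes, the last meaning the whole lineage with its precursors. Levels are given in CPM, UMI counts relative to the library total as computed by edgeR. All adjusted p-values of genes are from this test, by Benjamini-Hochberg at 0.05 over the genes tested in a comparison. Comparisons were PDMCAO minus sham (across ages, young, aged), aged minus young (sham, PDMCAO), their interaction and female minus male in microglia, and PDMCAO minus sham across ages and aged minus young after PDMCAO in the other types. Where a group had 0 counts, a fold is given as a bound against a floor of 3 counts over the group, and where it had 1 to 3 counts as a ratio of summed counts with a 95% counting interval. Both use counts summed over libraries, so neither measures spread between libraries. Gene lists, 21 by function and 8 of transcripts known from other cell types, were tested with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the lists of a comparison. A list was tested with at least 3 measured members. Shares of 16 cell types with at least 100 cells, in percent of kept cells, and the share of microglia with an Ifi27l2a UMI were compared by exact two-sided permutation, of surgery within age and sex and of age within surgery and sex.

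Genes are named by a rule that was also fixed beforehand. Ifi27l2a is given in every comparison. In microglia the 10 largest rises and 10 largest falls past the threshold with a mean of at least 10 counts per library are named (5 each for the interaction and sex, and in other cell types), without predicted genes, antigen receptor segments and, outside the sex comparison, Xist, Tsix and Y-linked genes. Members of the lists of other types are named as such. Results for 2 genes are not reported here. From each list past its test, up to 4 members with the smallest p in its direction and up to 2 past the threshold in the opposite direction may be named. Sequence shared with other genes was counted as 31-base stretches in the last 600 bases of a gene's transcripts. Genes with intron sequence were ranked on the annotation, for genes with at least 10 CPM.

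Alternatives were RLE normalization, no filter on low counts, DESeq2 1.42.0, no sex term, a model of 8 groups, only the groups compared, only libraries numbered 1, the replicate number as a block, and counts thinned to the smallest library. Others were no removal of doublets, a stricter cell filter (500 genes, 10% mitochondrial), Leiden resolution 2, each library left out, thinning to 2000 UMIs or not at all, log odds with an offset of 0.5, and percent of non-microglial cells. Lists without female PDMCAO aged 2, list settings in the other cell types, limits of 0.1 and 0.2 in place of 0.11 for mixed clusters and edgeR on cell counts were added after the data were seen. So were the oligodendrocyte lineage without the clusters in which precursor markers were above oligodendrocyte markers, and its largest cluster, cluster 0, alone. Other splits of the libraries were drawn up to 50 times with a fixed seed. Figures were made with matplotlib 3.10.9. Gene tests were not run in the other cell types, and unnamed cells were not analysed here. Choroid plexus cells (1819) were left out of gene tests though they outnumbered astrocytes (1696). The other types held few cells in several libraries.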

Results

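Droplet single-cell RNA sequencing (10X Chromium) measured the transcripts of single cells from dissociated brain of young and aged mice of both sexes. Brains were collected 14 days after a sham operation or after PDMCAO, the stroke surgery. The series title names Ifi27l2a, an interferon-inducible gene, together with inflammation of microglia in aging and stroke, and the design crosses surgery, age and sex. There were 12 libraries, of which 4 were sham (1 of each sex at each age) and 8 were PDMCAO (2 of each sex at each age). The labels number the libraries of a group but do not say that each came from a separate animal, so p-values measure the spread between these libraries, which may be technical.

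Total UMI counts in the sham libraries were 12172035 (male young 1), 8919415 (female young 1), 15072782 (male aged 1) and 6242608 (female aged 1). Those of the young PDMCAO libraries were 8770631 (male 1), 20204926 (male 2), 14349319 (female 1) and 13371025 (female 2). The aged PDMCAO libraries held 10523648 (male 1), 9225646 (male 2), 13543821 (female 1) and 25186976 (female 2) UMIs. After filtering, 30299 cells remained. The median depth per cell was 2892.5 to 4473 UMIs in 11 libraries and 10569 in female PDMCAO aged 2. Clusters were named from marker genes as oligodendrocyte-lineage-like (8882 cells), microglia-like (8587), endothelial-like (4533), choroid-plexus-like (1819), astrocyte-like (1696) and 11 smaller types. These are shortened below to the name of the type, and 942 cells stayed unnamed. Below, log2 fold changes carry their standard error, and group levels are mean ± SD in CPM after TMM normalization. They are over 8 PDMCAO and 4 sham libraries unless another n is given.

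Ifi27l2a was higher in microglia after PDMCAO than sham at both ages. Its level in CPM without TMM scaling was 29.96 ± 4.65 in young sham (SD, n = 2), 109 ± 11.5 in aged sham (n = 2), 280.1 ± 142 in young PDMCAO (n = 4) and 756 ± 151 in aged PDMCAO libraries (n = 4). The lowest PDMCAO library, a young one, had 118 and the highest sham library, an aged one, had 117. The log2 fold change of PDMCAO over sham was 3.21 ± 0.39 across ages (edgeR, adjusted p = 0.000970), 3.40 ± 0.57 in young mice (adjusted p = 0.0169) and 3.02 ± 0.53 in aged mice (adjusted p = 0.0149). All 4 aged PDMCAO libraries lay above all 4 young ones, 546 to 874 against 118 to 437. The age difference, 1.56 ± 0.38 after PDMCAO, missed the threshold in edgeR (adjusted p = 0.0810) and passed it in DESeq2 (adjusted p = 0.00165). In sham microglia it was 1.93 ± 0.58 (adjusted p = 0.734). The surgery effect was not shown to differ between ages (interaction -0.37 ± 0.68, adjusted p = 0.985). The difference between the sexes was 0.06 ± 0.31 (adjusted p = 0.9996). The young call was lost without male sham young 1 (adjusted p = 0.220), female sham young 1 (0.265) or male PDMCAO young 1 (0.0507). The aged call was lost without male sham aged 1 (0.124) or female sham aged 1 (0.227). A model of 8 groups ended both (adjusted p = 0.0651 in young and 0.0546 in aged mice). With only the groups compared in the fit, the young call ended (0.165) and the aged one passed (0.0492). The age difference in sham microglia passed with only the groups compared (5.1e-21), with no filter on low counts (6.3e-08) and with only libraries numbered 1 (3.0e-05). After PDMCAO it passed in the last 2 of these (8.4e-15 and 6.3e-06). The fit with only the sham groups compares 2 libraries with 2 beside a sex term, which leaves almost no freedom to estimate the spread. Its p of 5.1e-21 (edgeR) therefore does not measure spread between libraries. Without the filter, the number of called genes rose in every microglial comparison. The series title names the gene, so its direction is not independent evidence.

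More microglia also held at least 1 Ifi27l2a UMI after PDMCAO. With each cell thinned to 1000 UMIs, the share was 1.89% ± 0.0656 in young sham (SD, n = 2), 6.59% ± 0.889 in aged sham (n = 2), 14.9% ± 7.78 in young PDMCAO (n = 4) and 38.9% ± 4.36 in aged PDMCAO libraries (n = 4). Without thinning the shares were 3.92%, 15.8%, 33.4% and 73.8%. Thinning left out 14 shallower cells, all of them in aged PDMCAO libraries. The share was 22.7 percentage points higher after PDMCAO (exact two-sided permutation within age and sex, p = 0.0123) and 17.6 points higher in aged mice (exact permutation within surgery and sex, p = 0.0139). Each p is the smallest its permutations can give. In the same order of groups, oligodendrocytes, which make myelin, held a UMI in 0.582%, 1.18%, 2.22% and 8.48% of thinned cells, and astrocytes in 0.319%, 0.689%, 1.80% and 3.77%. Endothelial cells held one in 2.86%, 5.34%, 4.49% and 12.4%, above microglia in young sham only. Median depths before thinning were 2402, 3376.5, 3378 and 5932 UMIs in microglia, 3587, 3860, 3980 and 5472.5 in oligodendrocytes, and 1994, 2320, 2214 and 2301 in astrocytes. They were 2201, 2424.5, 2441 and 3021.5 in endothelial cells. Monocytes and neutrophils had more Ifi27l2a than microglia in every group, 981 ± 84.7, 1963 ± 691, 1571 ± 493 and 2806 ± 1195 CPM without TMM scaling (SD, n = 2, 2, 4 and 4). These rest on 21, 20, 41 and 197 cells. By mean so did T and NK cells, with 355 ± 394, 283 ± 241, 1037 ± 327 and 2106 ± 828 over 22, 61, 97 and 631 cells (same n). Any such cells or RNA in other types were not separated.

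**Figure D1:**
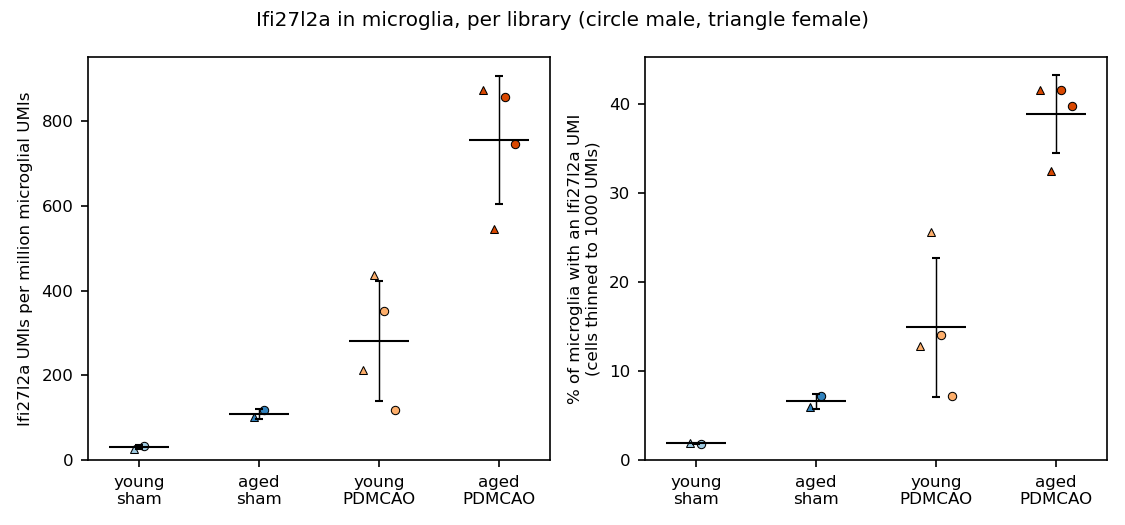
Ifi27l2a in microglia of each library, by age and surgery. The left panel gives Ifi27l2a in CPM of microglial UMIs without TMM scaling and the right panel the percent of microglia with at least 1 Ifi27l2a UMI after thinning each cell to 1000 UMIs; circles are male and triangles female libraries, and bars are the mean ± SD. The aged PDMCAO libraries (546 to 874 CPM) lie above all others.

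Ifi27l2a (ENSMUSG00000079017) is a protein-coding gene on chromosome 12 of GRCm38 (mm10), from 103442167 to 103443680 on the minus strand, with 4 exon blocks of 463 bases in all. Its neighbours are Ifi27 (103434211 to 103440239, plus strand) and its paralog Ifi27l2b (103450898 to 103457223, minus strand). Microglia held 22310 UMIs of Ifi27l2a and 4 of Ifi27l2b. In the last 600 bases of their transcripts, 6.00% of the 31-base stretches of Ifi27l2a also occur in Ifi27l2b, the gene that shares the most of them. Where its UMIs lie along the transcript was not examined, so the share of UMIs affected is not known.

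The cell composition of the tissue was compared as percent of kept cells. Microglia made up 19.2% ± 0.807 of cells in young sham, 21.9% ± 2.78 in aged sham, 27.2% ± 7.04 in young PDMCAO and 39.3% ± 8.63 in aged PDMCAO libraries (SD, n = 2, 2, 4 and 4). T and NK cells were 0.375% ± 0.198, 1.28% ± 0.163, 0.920% ± 0.563 and 8.23% ± 4.47 in the same order. Dendritic cells were 0.0689% ± 0.0311, 0.119% ± 0.128, 0.296% ± 0.193 and 2.19% ± 1.03. Border macrophages, the macrophages of meninges and vessels, were 0.630% ± 0.0948, 0.758% ± 0.578, 1.41% ± 0.953 and 3.81% ± 1.22. Oligodendrocyte-lineage cells were 43.8% ± 4.40, 41.9% ± 8.57, 34.3% ± 16.5 and 11.3% ± 5.74. Astrocytes were 7.84% ± 1.58, 7.31% ± 0.360, 5.14% ± 2.30 and 3.10% ± 1.47. B and plasma cells were 5.24% ± 6.84 of aged PDMCAO libraries, of which female PDMCAO aged 1 alone had 15.3%. Of 16 types, 0 passed after adjustment in either comparison (exact two-sided permutation), in every planned setting. The smallest p these permutations allow was 0.0123 for surgery and 0.0139 for age, so a type could pass only if several types reached it. With only libraries numbered 1 the smallest was 0.125, so no type could pass there. The counts of 0 therefore do not show that shares were unchanged. Unadjusted exact p under 0.05 for PDMCAO minus sham were reached by microglia (12.7 points, p = 0.0370, adjusted p = 0.148), oligodendrocyte lineage (-20.0 points, p = 0.0494), astrocytes (-3.46 points, p = 0.0247), border macrophages (1.91 points, p = 0.0370) and dendritic cells (1.15 points, p = 0.0247). For aged minus young they were T and NK cells (5.18 points, p = 0.0139, adjusted p = 0.111), microglia (9.00, p = 0.0417), oligodendrocyte lineage (-16.0, p = 0.0417), dendritic cells (1.28, p = 0.0278), ependymal cells (-1.22, p = 0.0139) and neuroblasts (-0.790, p = 0.0417), each an exact permutation. The other types differed by at most 3.75 points with surgery (T and NK cells, exact p = 0.123) and 3.25 points with age (B and plasma cells, exact p = 0.139). An edgeR model of cell counts, added after the data were seen, called 1 type in each comparison, dendritic cells with surgery (log2 fold change 3.19 ± 0.77, adjusted p = 0.0113) and T and NK cells with age (2.49 ± 0.62, adjusted p = 0.0157). The shares are of cells recovered after dissociation and filtering.

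**Figure D2:**
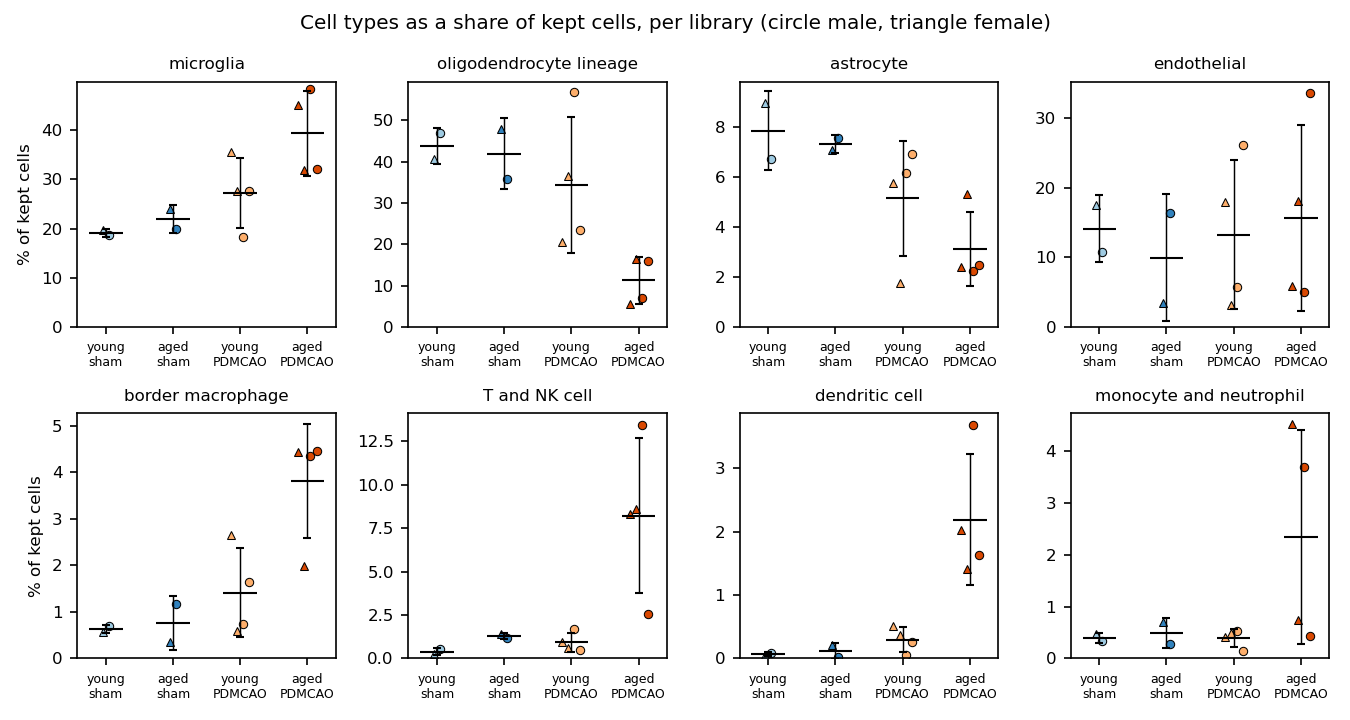
Percent of kept cells of 8 cell types in each library, by age and surgery, with circles for male and triangles for female libraries and bars for the mean ± SD. T and NK cells reach 13.5% in aged PDMCAO libraries, with a lowest value of 2.53% there.

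In microglia of both ages together, the genes furthest above sham after PDMCAO were Gpnmb (PDMCAO 219 ± 47.6, sham 3.23 ± 5.99 CPM), Apoc4 (76.4 ± 46.8 and 3.65 ± 4.27), Ms4a7 (66.2 ± 37.7 and 2.57 ± 3.84) and Mmp12, a macrophage elastase (35.0 ± 13.1 and 5.32 ± 7.01). Gpnmb and Ms4a7 are known from activated macrophages and border macrophages, and for these 4 genes no fold is given because both young sham libraries had 0 counts. Spp1, which codes for osteopontin, rose from 99.7 ± 108 to 5903 ± 2299 CPM (log2 fold change 6.88 ± 0.55, adjusted p = 0.000149). All 8 PDMCAO libraries lay above all 4 sham libraries, as for Gpnmb, Apoc4 and Ms4a7. Clec4d, Htr2b, Saa3 and Dram1 had 0 counts in sham microglia and were at least 10.2-fold, 11.4-fold, 7.51-fold and 8.34-fold higher, against a floor of 3 counts over the group. Adam8 had 3 sham counts and a ratio of 31.7 (counting interval 10.8 to 154). The largest falls were in the heat shock gene Hspa1a (-2.26 ± 0.26, adjusted p = 0.000798, 88.8 ± 30.2 after PDMCAO and 555 ± 563 CPM in sham), Fbxo2 (-1.98), Slc36a2 (-1.91), Slc5a10 (-1.90), Sema4b (-1.89), Zfp58 (-1.67) and Upk1b (-1.62). Zfp324 (-1.61), the fructose transporter gene Slc2a5 (-1.59 ± 0.14, adjusted p = 0.000200, 171 ± 60.0 and 493 ± 47.3 CPM) and Gp9 (-1.50) followed. Of the 31-base stretches of Zfp58, 51.5% also occur in the predicted gene Gm26965, so its value is uncertain.

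Of 11254 genes tested in microglia, 667 were higher and 419 lower after PDMCAO (edgeR), while DESeq2 called 840 and 354 and a model of 8 groups 456 and 188. Without female PDMCAO aged 2, the deepest library, which was singled out after the data were seen, the counts were 1513 and 1110. The total of 1086 became 498 without male sham young 1, 427 without female sham young 1, 572 without male sham aged 1 and 413 without female sham aged 1. Different clusters held the class. Clusters 1 and 3 held 45.7% and 52.5% of microglia in young sham, and 20.1% and 7.53% in aged PDMCAO libraries, where clusters 5, 12, 9 and 18 held 29.4%, 15.6%, 13.6% and 12.4%. Cluster 18 held 49.0% of the microglia of female PDMCAO aged 2, which gave 277 of its 284 cells.

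Interferon-response genes rose together. Of 32 measured, 30 were higher over all genes (32 adjusted over the list alone), with a median log2 fold change of 2.39, among them Ifitm3 (3.46 ± 0.37), Lgals3bp (2.48 ± 0.24), Rtp4 (2.30) and Slfn5 (3.56). Genes known to rise in disease-associated microglia followed (24 of 29, 28 adjusted over the list alone, median 1.55), with the fatty-acid binding protein gene Fabp5 (3.40 ± 0.23, adjusted p = 0.000141), the growth factor Igf1 (4.91 ± 0.36), the receptor Axl (3.01) and Itgax (2.78). Of 26 homeostatic microglia genes 15 fell (19 adjusted over the list alone, median -0.62), including the purinergic receptor P2ry12 (-1.30 ± 0.12, adjusted p = 0.000200, 1441 ± 553 and 3378 ± 551 CPM), Crybb1 (-1.46) and Selplg (-1.06). Chemokines (10 of 17, 14 adjusted over the list alone, median 1.97) included Ccl5 (4.42), Cxcl10 (2.65), Cxcl14 (2.49) and Ccl4 (1.04). Ccl5 is also made by T cells. NF-kB and inflammatory cytokine genes (15 of 29 higher, 19 adjusted over the list alone, median 0.82) included the cyclooxygenase gene Ptgs2 (3.54), Il1rn (3.66) and Tnfaip2 (1.31). Il6 fell (-0.80 ± 0.19, adjusted p = 0.0252). Class I antigen presentation (10 of 19, 15 adjusted over the list alone, median 0.66) included H2-Q7 (2.35), H2-D1 (1.41) and H2-K1 (1.09). Complement genes (4 of 12, 4 adjusted over the list alone, median 0.19) included C3 (3.32) and C4b (2.70), the latter with 34.7% of its sequence shared with C4a.

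Lipid handling genes were higher (13 of 28, 14 adjusted over the list alone, median 0.58). They included Apoe, the main lipid carrier of the brain, at 44673 ± 15173 CPM after PDMCAO and 5261 ± 4829 in sham (3.63 ± 0.37, adjusted p = 0.000402), the lipid droplet gene Plin2 (2.11 ± 0.18) and Fabp3 (4.44). Glycolysis and hypoxia genes (12 of 22, 14 adjusted over the list alone, median 0.63) included Hif1a (1.55 ± 0.13), Vegfa (1.68) and Gpi1 (0.71). Senescence genes (5 of 16, 7 adjusted over the list alone, median 0.40) included Lmnb1 (1.91), which falls in senescent cells, and Cdkn1a (1.48). The reactive astrocyte list (11 of 19, 13 adjusted over the list alone, median 1.36) was led by Vim (2.61 ± 0.21), an intermediate filament gene that microglia also express. Transcripts known from border macrophages (4 of 7, 5 adjusted over the list alone, median 2.90) included Dab2 (1.81), Pf4 (3.40) and Folr2 (4.03).

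These 12 lists, from interferon response to border macrophage transcripts, hold with an estimated correlation, out of 23 of 29 past camera's test. The other 11 do not. Those higher were class II antigen presentation, with Cd74 at 2.24 (4 of 9, 4 adjusted over the list alone, adjusted p = 0.449 with an estimated correlation), lysosome (11 of 34, 17 adjusted over the list alone, p = 0.261) and oxidative phosphorylation (11 of 40, 21 adjusted over the list alone, p = 0.387). So were ribosomal proteins (20 of 50, 39 adjusted over the list alone, adjusted p = 0.144 with an estimated correlation), cell cycle (4 of 24, 5 adjusted over the list alone, p = 0.357) and disease-associated oligodendrocyte (8 of 20, 10 adjusted over the list alone, p = 0.131). In the lysosome list Lgmn (-0.43 ± 0.12), which is also a microglial identity gene, fell. Transcripts of monocytes and neutrophils (median 1.71, adjusted p = 0.467 with an estimated correlation) and of T and NK cells (2.33, p = 0.325) were higher. Those of myelin (-0.73, adjusted p = 0.485 with an estimated correlation), oligodendrocytes (-0.63, p = 0.467) and astrocytes (-0.52, p = 0.366) were lower. The 6 lists not past the test were immediate-early and stress genes (median -0.14), angiogenesis (0.36), blood-brain barrier (0.30), and transcripts of endothelial (0.50), red blood (-0.34) and neuronal, ependymal and choroid plexus cells (-0.48). Without female PDMCAO aged 2, oxidative phosphorylation had 36, ribosomal proteins 47 and cell cycle 8 genes higher.

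**Figure D3:**
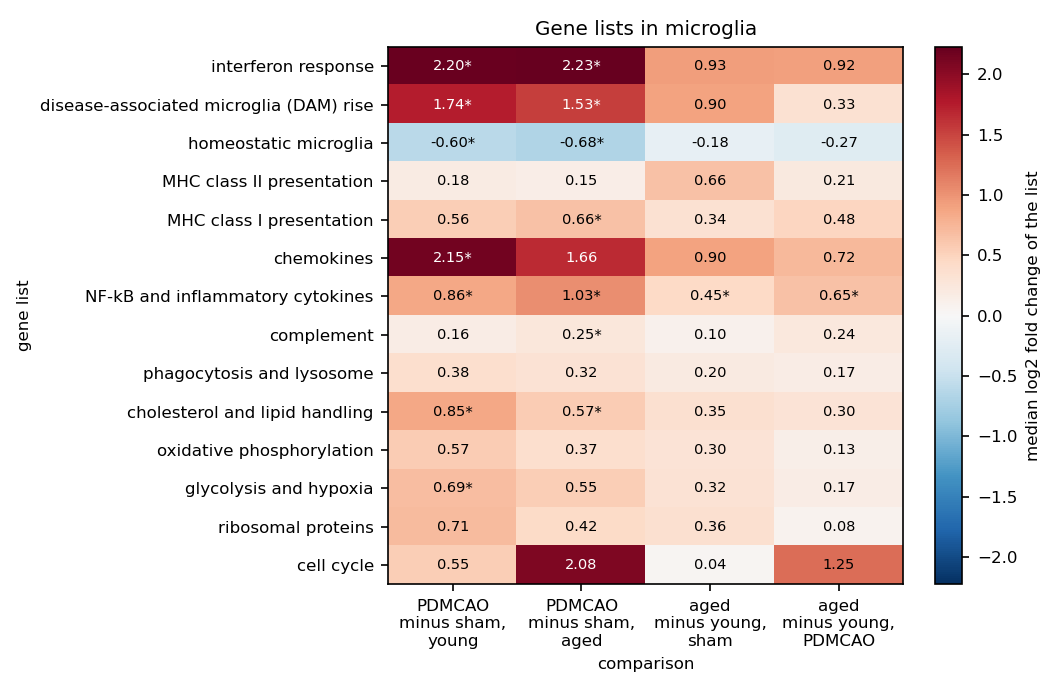
Median log2 fold change of the genes of 14 lists in microglia, as a heat map with a row per list and a column per comparison. An asterisk marks an adjusted p under 0.05 with an estimated correlation.

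In young microglia, Gpnmb, Apoc4, Ms4a7 and Mmp12 had 0 counts in both sham libraries and were at least 163-fold, 43.8-fold, 35.5-fold and 35.4-fold higher after PDMCAO. The same held for Atp6v0d2 (at least 10.9-fold), Adam8 (8.54-fold), Dkk2 (7.65-fold), Asb11 (4.43-fold) and Tmem178 (4.36-fold). Spp1 rose from 15.8 ± 14.8 (n = 2) to 5957 ± 2849 CPM (n = 4; 8.63 ± 0.85, adjusted p = 0.00181), Apoe from 1589 ± 894 to 39902 ± 7732 (4.71 ± 0.56, adjusted p = 0.00382) and Itgax by 4.02. The cytokine gene Il1b rose from 61.3 ± 33.6 to 513 ± 146 CPM (3.10 ± 0.44, adjusted p = 0.00733), Ifitm3 by 3.93, Ifi204 by 3.73 and the invariant chain Cd74 by 3.11, in all 4 PDMCAO libraries above both sham libraries. Hspa1a (-2.94 ± 0.37), Upk1b (-1.40), Lrba (-1.38), Slc2a5 (-1.30), Ncaph (-1.20), Gp9 (-1.10), Ecscr (-1.10), P2ry13 (-1.06), Siglece (-1.04) and P2ry12 (-1.04 ± 0.17, adjusted p = 0.0123) fell. In all, 168 genes were higher and 27 lower (641 and 366 without female PDMCAO aged 2, 295 and 64 in DESeq2, 93 and 7 in a model of 8 groups). Interferon response (12 of 32, 28 adjusted over the list alone, median 2.20) and disease-associated microglia genes (18 of 29, 26 adjusted over the list alone, median 1.74) were higher and homeostatic genes lower (6 of 26, 17 adjusted over the list alone, median -0.60). These and 6 other lists hold with an estimated correlation, out of 23 past the test: chemokines (median 2.15, or 1.40 with 4 genes at their bounds), NF-kB (0.86), lipid handling (0.85), glycolysis (0.69), reactive astrocyte (1.52, or 1.36 with 1 gene at its bound) and border macrophage transcripts (2.07). Transcripts of oligodendrocytes (median 0.62, adjusted p = 0.554 with an estimated correlation) and astrocytes (0.63, p = 0.534) were higher in these cells after PDMCAO, as were myelin genes (0.67, p = 0.554). Those of monocytes and neutrophils had a median of -0.47 beside a mean of 0.76. The total of 195 became 11 without male sham young 1, 25 without female sham young 1, 112 without male PDMCAO young 1 and 111 without female PDMCAO young 1. It became 128 without male PDMCAO aged 1, 121 without female PDMCAO young 2 and 1007 without female PDMCAO aged 2.

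In aged microglia, Gpnmb rose from 6.46 ± 8.11 to 235 ± 22.96 CPM (5.58 ± 0.73, adjusted p = 0.00735, n = 2 and 4), Spp1 from 184 ± 80.7 to 5849 ± 2053 (5.12 ± 0.69, adjusted p = 0.00537) and the fibronectin gene Fn1 from 2.79 ± 1.65 to 122 ± 16.7 (5.20 ± 0.53, adjusted p = 0.00274). Lgals3bp (2.71), Rnf213 (2.70), Bst2 (1.65) and Trim30a (1.35), all interferon-induced, rose too, as did the chemokine Cxcl10 (2.89 ± 0.53, adjusted p = 0.0160), Ptgs2 (3.02), C3 (3.37) and the cholesterol hydroxylase gene Ch25h (4.13), each in all 4 PDMCAO libraries above both sham libraries. Htr2b, Clec4d, Dram1 and AI427809 had 0 sham counts and were at least 8.86-fold, 7.04-fold, 6.17-fold and 4.50-fold higher. Hpse, Ccl8 and Oas2 had 1 sham count and ratios of 56.8 (counting interval 10.1 to 2249), 28.7 (counting interval 5.09 to 1139) and 26.9 (counting interval 4.76 to 1067). P2ry12 fell from 2904 ± 101.5 to 988 ± 64.8 CPM (-1.56 ± 0.17, adjusted p = 0.00274), with Slc2a5 (-1.87) and Crybb1 (-1.91). The 10 largest falls were Sez6l2 (-2.92), Hapln2 (-2.81), Aplp1 (-2.75), Gstm7 (-2.62), Mog (-2.55), Dusp26 (-2.55), Mal (-2.52), Fez1 (-2.48), Slc36a2 (-2.48) and Omg (-2.46), of which Mog, Mal, Omg and Hapln2 are oligodendrocyte genes. In all, 325 genes were higher and 229 lower (1168 and 764 without female PDMCAO aged 2, 520 and 298 in DESeq2, 124 and 59 in a model of 8 groups, 14 and 2 with only the groups compared). Interferon response (29 of 32, 32 adjusted over the list alone, median 2.23) and disease-associated microglia genes (19 of 29, 24 adjusted over the list alone, median 1.53) rose and homeostatic genes fell (12 of 26, 16 adjusted over the list alone, median -0.68). Of 23 lists past the test, these and 8 others hold with an estimated correlation: class I presentation (median 0.66), NF-kB (1.03), complement (0.25), lipid handling (0.57), senescence (0.68), reactive astrocyte (0.83), astrocyte transcripts (-1.90) and border macrophage transcripts (2.90). Myelin (3 of 20 lower, 17 adjusted over the list alone, median -2.07, adjusted p = 0.127 with an estimated correlation) and oligodendrocyte transcripts (-1.95, p = 0.114) were lower, and chemokines higher (1.66, or 1.24 with 1 gene at its bound, p = 0.0782). The total of 554 became 21 without male sham aged 1 and 1 without female sham aged 1. It became 337 without female PDMCAO young 1, 293 without male PDMCAO aged 1, 279 without male PDMCAO aged 2 and 1932 without female PDMCAO aged 2.

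Between aged and young sham microglia, 3 genes passed the test (edgeR), all higher in aged mice. They were the sialic-acid receptor gene Cd22 (22.01 ± 1.06 against 3.28 ± 0.382 CPM, n = 2 and 2; 2.72 ± 0.32, adjusted p = 0.0451), the retinoid receptor gene Rxrg (15.9 ± 5.13 against 2.31 ± 0.0772; 2.71 ± 0.35, adjusted p = 0.0466) and Ly9 (59.7 ± 1.84 against 20.7 ± 1.64; 1.52 ± 0.20, adjusted p = 0.0466), each with both aged libraries above both young ones. DESeq2 called 36 genes higher and 1 lower, and edgeR without female PDMCAO aged 2 called 42 and 4. With RLE normalization, in a model of 8 groups and with counts thinned to the smallest library, 0 genes passed. More passed with only the groups compared, a fit of 2 against 2 libraries with a sex term that leaves almost no freedom to estimate the spread. Apoe (2.51 ± 0.52, adjusted p = 0.258), Spp1 (3.61, 0.244), Itgax (2.45, 0.0845), Il1b (2.58, 0.154) and Vim (2.37, 0.0729) had higher means in aged sham microglia but missed the threshold. Of 29 lists, 18 passed the test, and 2 of them hold with an estimated correlation, NF-kB and inflammatory cytokines (0 of 29, 3 adjusted over the list alone, median 0.45, adjusted p = 0.0449) and reactive astrocyte (0 of 19, 3 adjusted over the list alone, median 0.83, adjusted p = 0.0265). Disease-associated microglia genes (12 of 29 higher adjusted over the list alone, median 0.90, adjusted p = 0.0644 with an estimated correlation) and interferon response (6 of 32 adjusted over the list alone, median 0.93, p = 0.130) do not. The 3 calls became 0 without any 1 of the 4 sham libraries, female PDMCAO young 1, male PDMCAO aged 1, female PDMCAO aged 1 or male PDMCAO aged 2, 8 without male PDMCAO young 2 and 46 without female PDMCAO aged 2.

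Between aged and young microglia after PDMCAO (n = 4 and 4), 57 genes were higher and 97 lower (581 and 387 without female PDMCAO aged 2, 230 and 241 in DESeq2). The total of 154 was 1 in a model of 8 groups, 1 with only the groups compared in the fit and 23 (14 higher, 9 lower) with counts thinned to the smallest library. The B-cell chemoattractant Cxcl13 rose from 2.68 ± 3.37 in young to 117 ± 58.4 CPM in aged mice (5.45 ± 0.90, adjusted p = 0.0353), Fn1 from 26.3 ± 14.2 to 122 ± 16.7 (2.28 ± 0.31, adjusted p = 0.0192) and Rxrg from 6.23 ± 1.65 to 33.2 ± 5.67 (2.43 ± 0.19, adjusted p = 0.000950). Ccl8 (3.45), Kcnj12 (2.94), Ildr2 (2.93), the interferon-induced sialoadhesin gene Siglec1 (2.53), Ctla2a (2.29), Ass1 (2.51, 34.4% of its sequence shared with Gm5424) and Oas1a (2.28, 75.3% shared with Oas1g) also rose. The cytokine gene Tnf (619.8 ± 122 against 257 ± 56.2 CPM; 1.26 ± 0.21, adjusted p = 0.02499) was higher and P2ry12 (-0.93 ± 0.14, adjusted p = 0.0196) lower, each with no overlap between the 4 aged and 4 young libraries. The largest falls were genes known from astrocytes or oligodendrocytes, such as Mlc1 (-3.10), Gja1 (-2.78), Slc6a11 (-2.54), Mal (-2.89), Mog (-2.70) and Omg (-2.60), beside Glrb (-3.50), Sept4 (-2.61), Shisa4 (-2.59) and Pantr1 (-2.56). Of 19 lists past the test, 4 hold with an estimated correlation: NF-kB and inflammatory cytokines (2 of 29, 10 adjusted over the list alone, median 0.65), senescence (2 of 16, 3 adjusted over the list alone, median 0.40), reactive astrocyte (1 of 19, 8 adjusted over the list alone, median 0.66) and astrocyte transcripts (7 of 13 lower, 11 adjusted over the list alone, median -2.11). Interferon response (4 of 32 higher, 23 adjusted over the list alone, median 0.92) had an adjusted p = 0.0692 with an estimated correlation, and class I presentation (0.48) one of 0.0865. Homeostatic genes (median -0.27, adjusted p = 0.112 with an estimated correlation), myelin (-2.14, p = 0.0865) and oligodendrocyte transcripts (-1.86, p = 0.0766) were lower. The 154 became 60 without male sham young 1, 61 without female sham young 1, 59 without male sham aged 1, and 60 without female sham aged 1. It became 71 without male PDMCAO young 1, 15 without female PDMCAO young 1, 28 without male PDMCAO aged 1 and 80 without female PDMCAO aged 1. It was 1 without male PDMCAO young 2, 16 without female PDMCAO young 2, 16 without male PDMCAO aged 2 and 968 without female PDMCAO aged 2.

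Whether the surgery effect in microglia depends on age was tested as an interaction. For 0 genes did it pass (edgeR), with 547 at an unadjusted p under 0.05, 1 without female PDMCAO aged 2, and 16 lower in DESeq2. Of 29 lists 13 passed camera's test and 0 hold with an estimated correlation. The surgery effect on myelin (median difference -2.79, adjusted p = 0.119 with an estimated correlation) and on astrocyte transcripts (-2.35, p = 0.0721) was lower in aged microglia, as was that on disease-associated microglia genes (-0.28, p = 0.664). Between the sexes 5 genes passed in microglia, all on a sex chromosome. Tsix had 3 male counts and a ratio of 159 (counting interval 54.2 to 774), Eif2s3y had 0 female counts and was at least 598-fold lower in female mice, and Ddx3y (-7.83 ± 0.43, adjusted p = 4.1e-05), Uty and Kdm5d were also lower. Without female PDMCAO aged 2 the sex count was 13, and of 5 lists past the test 0 hold with an estimated correlation.

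Cells of the oligodendrocyte lineage, precursors included, had higher interferon-response transcripts after PDMCAO. Ifit1 rose from 0.802 ± 0.123 to 34.4 ± 28.6 CPM (4.86 ± 0.62, adjusted p = 0.0346), with Ifit3b (4.91, not a member of the interferon list), Ifit3 (4.76, 30.9% of its sequence shared with Ifit3b), Usp18 (4.38), Irf7 (3.96), Oasl2 (3.84) and Rtp4 (2.71 ± 0.32, adjusted p = 0.0134). The complement gene C4b (1.65 ± 0.18, adjusted p = 0.0109, 285 ± 221 and 123 ± 125 CPM) and the protease inhibitor gene Serpina3n (2.81 ± 0.30, adjusted p = 0.0109), both known from oligodendrocytes in disease, were higher, as were H2-T23 (2.21), H2-K1 (1.21) and H2-D1 (1.60). The kinase gene Sgk1 was lower (-1.40 ± 0.21, adjusted p = 0.0466). Ifi27l2a was 198 ± 216 against 21.6 ± 13.9 CPM and missed the threshold (3.06 ± 0.80, adjusted p = 0.404). Of 11735 genes, 19 were higher and 1 lower (edgeR; 138 and 61 without female PDMCAO aged 2), while DESeq2 called 117 in all. There were 5 calls with no doublets removed, 5 with the stricter cell filter, 10 at Leiden resolution 2, 13 with mixed clusters from 0.2, 34 with no filter on low counts and 359 with only libraries numbered 1. The replicate block gave 17, of which 9 were among the 20. The lineage was made up of different clusters in each group. Cluster 0 held 75.1% of it in young sham, 62.2% in aged sham, 70.7% in young PDMCAO and 36.6% in aged PDMCAO libraries, and cluster 26, of precursors, 0.830%, 0.397%, 1.78% and 5.22%. Clusters 23 and 43 came from female PDMCAO aged 2 alone. Without the precursor clusters 26 and 43 there were 5 calls, with C4b and Serpina3n among them (adjusted p = 0.00507 for each), while the 7 interferon genes missed the threshold (0.0794 to 0.267). In cluster 0 alone there were 23 calls, 5 of them among the 20, with Usp18 (adjusted p = 0.0261), C4b (0.0355), Serpina3n (0.0264) and H2-K1 (0.0431), while Ifit3 (0.218), Irf7 (0.0651) and Rtp4 (0.808) missed it. Of 18 lists past the test, 4 hold with an estimated correlation: interferon response (7 of 29, 23 adjusted over the list alone, median 2.20), class I presentation (3 of 19, 11 adjusted over the list alone, median 1.48), disease-associated oligodendrocyte (4 of 21, 10 adjusted over the list alone, median 0.66) and reactive astrocyte (4 of 17, 9 adjusted over the list alone, median 1.60). Microglial genes known from disease were higher too (median 0.88, adjusted p = 0.127 with an estimated correlation). Glycolysis genes had a median of -0.12 and a mean of 0.06 beside a test for lower values (adjusted p = 0.240 with an estimated correlation). The 20 calls became 1, 0, 1 and 0 without male sham young 1, female sham young 1, male sham aged 1 and female sham aged 1. They became 2 without male PDMCAO young 1, 5 without female PDMCAO young 1, 8 without male PDMCAO aged 1, 3 without female PDMCAO aged 1, 13 without male PDMCAO young 2, 3 without male PDMCAO aged 2 and 199 without female PDMCAO aged 2.

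Between aged and young cells of the oligodendrocyte lineage after PDMCAO (n = 4 and 4), C4b rose from 80.1 ± 24.1 to 491 ± 38.1 CPM (2.61 ± 0.20, adjusted p = 0.000341), Serpina3n from 26.5 ± 10.3 to 275 ± 81.3 (3.37 ± 0.30, adjusted p = 0.00109) and the sodium pump regulator gene Fxyd7 from 1.90 ± 1.08 to 56.1 ± 11.5 (4.94 ± 0.39, adjusted p = 0.000341), with no overlap between libraries. Cdh8 (5.49), Klk8 (5.43), Adgrg6 (4.84), Art3 (3.39), Socs3 (1.93), H2-K1 (1.47) and Rtp4 (2.32) were higher as well. The myelin genes Mal (2547 ± 219 against 4648 ± 244 CPM; -0.87 ± 0.11, adjusted p = 0.0101), Opalin (-0.82) and Mog (-0.64) fell, as did Ptgds (-0.89), the glycolytic genes Tpi1 (-0.89) and Gpi1 (-0.59), Hist1h1c (-2.02), Mt2 (-1.67), Adgrg1 (-1.24), Gsto1 (-1.08) and the astrocyte gene Gjb6 (-2.83). In all, 52 genes were higher and 29 lower (201 and 205 without female PDMCAO aged 2, 334 and 161 in DESeq2). Of 20 lists past the test, 3 hold with an estimated correlation: interferon response (1 of 29, 20 adjusted over the list alone, median 1.66), disease-associated oligodendrocyte (4 of 21, 12 adjusted over the list alone, median 1.05) and reactive astrocyte (3 of 17, 7 adjusted over the list alone, median 1.39). Myelin genes were lower (3 of 20, 11 adjusted over the list alone, median -0.39, adjusted p = 0.150 with an estimated correlation). The 81 calls became 43, 41, 41 and 45 without male sham young 1, female sham young 1, male sham aged 1 and female sham aged 1. They became 22 without male PDMCAO young 1, 25 without female PDMCAO young 1, 45 without male PDMCAO aged 1 and 139 without female PDMCAO aged 1. They were 19 without male PDMCAO young 2, 30 without female PDMCAO young 2, 39 without male PDMCAO aged 2 and 406 without female PDMCAO aged 2. Cluster 23 held 76.3% of oligodendrocyte-lineage cells of female PDMCAO aged 2. Cluster 0 held 70.7% of the lineage in young and 36.6% in aged PDMCAO libraries, cluster 10 held 7.65% and 14.2%, and precursor cluster 26 held 1.78% and 5.22%. Without the precursor clusters 79 genes were higher and 38 lower, and Rtp4 (adjusted p = 0.102) and Mog (0.0593) missed the threshold. In cluster 0 alone 18 were higher and 14 lower. C4b (2.52), Serpina3n (2.76), Fxyd7 (5.66), Cdh8 (4.90), Tpi1 (-0.86) and Mt2 (-1.66) passed there, while Mal (adjusted p = 0.146), Opalin (0.417), Mog (0.232), Ptgds (0.307) and H2-K1 (0.131) missed it and Rtp4 turned direction (-1.20, adjusted p = 0.698).

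In endothelial cells 0 of 9581 genes passed for PDMCAO minus sham (edgeR), with 281 at an unadjusted p under 0.05 and 4 higher and 1 lower in DESeq2. There were 20 higher and 8 lower without female PDMCAO aged 2. Ifi27l2a was 141 ± 99.6 against 60.5 ± 32.9 CPM (1.09 ± 0.41, adjusted p = 1.00000). Selp, the gene of the adhesion molecule P-selectin, was at least 16.1-fold higher against 0 sham counts. Between aged and young PDMCAO endothelial cells (n = 4 and 4), the class I gene H2-Q7 (213 ± 60.5 against 39.9 ± 26.0 CPM; 2.47 ± 0.33, adjusted p = 0.0242) and Lypd1 (1.70 ± 0.27, adjusted p = 0.0335) were higher in all 4 aged libraries. Lower were Cryab (-2.55 ± 0.23, adjusted p = 0.000177), Nnat (-3.47), Opalin (-2.83), Gpr37l1 (-2.72) and the glutamate transporter gene Slc1a2 (-2.23), several of them known from oligodendrocytes or astrocytes. Gpm6b (-2.10) was also lower and lies outside the rule for named genes, since it was chosen after its value was seen. These 8 calls (60 higher and 37 lower without female PDMCAO aged 2, 25 and 54 in DESeq2) became 1 without male sham aged 1, male PDMCAO young 2 or male PDMCAO aged 2, 3 without female PDMCAO young 1 or 2, 5 without male sham young 1 or male PDMCAO aged 1, and 26 without female PDMCAO aged 1. The class sat in different clusters, with cluster 20 holding 84.7% of endothelial cells of female PDMCAO aged 2 and 0% in young PDMCAO libraries. Interferon response (10 of 30 higher adjusted over the list alone, median 0.59, adjusted p = 0.148 with an estimated correlation) and oligodendrocyte transcripts (median -1.95, p = 0.0798) and astrocyte transcripts (-1.87, p = 0.0798) moved in opposite directions. Of 16 lists past the test for surgery and 13 for age, 0 hold with an estimated correlation. Stress genes, called lower with surgery, had a median of 0.06 and a mean of -0.04 (adjusted p = 0.606 with an estimated correlation).

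In astrocytes 0 of 7180 genes passed for PDMCAO minus sham (edgeR), with 313 at an unadjusted p under 0.05, 2 higher in DESeq2 and 12 higher and 2 lower without female PDMCAO aged 2. Gfap, the filament gene used as an astrocyte marker, was 109 ± 88.7 after PDMCAO against 74.4 ± 20.8 CPM in sham (0.33 ± 0.47, adjusted p = 0.956) and Ifi27l2a 31.9 ± 25.6 against 9.10 ± 10.1 (1.57 ± 0.75, adjusted p = 0.940). Between aged and young PDMCAO astrocytes the gene listed as PISD passed, at 422 ± 135 against 123 ± 24.5 CPM (1.78 ± 0.25, adjusted p = 0.0101, all 4 aged above all 4 young libraries). The interferon-response gene Rtp4 was at 52.9 ± 20.5 against 6.12 ± 2.05 CPM and missed the threshold (3.20 ± 0.57, adjusted p = 0.0582). The count of 1 became 6 without female PDMCAO young 1, 2 without male PDMCAO aged 1, 22 without female PDMCAO aged 1, 0 without male PDMCAO young 2, 3 without male PDMCAO aged 2 and 9 without female PDMCAO aged 2 (13 higher and 20 lower in DESeq2). The class sat in different clusters here too. Cluster 38 held 61.7% of astrocytes of female PDMCAO aged 2 and 0% in young PDMCAO libraries, and cluster 8 held 56.7% in young and 36.8% in aged PDMCAO libraries. Interferon response was higher with surgery (median 0.64 over 11 genes, adjusted p = 0.224 with an estimated correlation) and with age (0.83, p = 0.327), and myelin lower with age (18 of 20 adjusted over the list alone, median -3.03, p = 0.315). Of 10 lists past the test for surgery and 9 for age, 0 hold with an estimated correlation.

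Female PDMCAO aged 2 differed from the other libraries in every cell type tested. Genes with the most intron sequence were higher, relative to genes with the least, than in the other aged PDMCAO libraries, by a difference of median log2 ratios of 1.64 in microglia, 1.55 in endothelial cells, 2.19 in astrocytes and 1.75 in oligodendrocytes. In the other 11 libraries the highest such difference was 0.202. Of its barcodes, 16.1% were over the mitochondrial limit, against 0.119% to 3.22% in the others. The common dispersion of microglial counts was 0.0954 with it and 0.0185 without it.

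**Figure D4:**
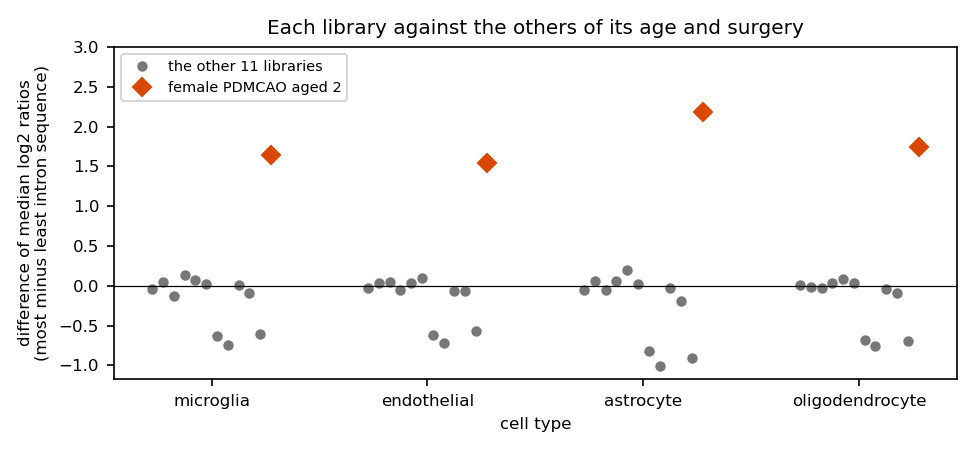
Difference between the median log2 ratios of genes with the most and the least intron sequence, for each library against the other libraries of its age and surgery, in 4 cell types. The diamond is female PDMCAO aged 2 (1.55 to 2.19) and grey points are the other 11 libraries (at most 0.202), of which the other 3 aged PDMCAO libraries lie below 0 because their comparison group contains it.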

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

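The tests of intron sequence, of transcripts of other types in endothelial cells and of these against cell shares, and the use of spread and of the whole and uncalled interferon list in oligodendrocytes, were chosen only after the results they weigh were seen. Of 44 Dixon tests, on linked measures of young or aged PDMCAO libraries, 9 set a library apart. Such tests cannot be weighed against chance (1 in 20). Of the 9, 4 were values of female PDMCAO aged 2. These were its median depth of 10569 UMIs per cell, 16.1% of barcodes over the mitochondrial limit, 5.30% astrocytes and 1.98% border macrophages. Female PDMCAO aged 1 had 2567 kept cells, 15.3% B and plasma cells and 0.974% ependymal cells. Female PDMCAO young 2 had 3.22% of barcodes over the mitochondrial limit, and male PDMCAO young 1 had 1.18% red blood cells.

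The first pattern is that female PDMCAO aged 2 stands apart in every cell type tested, with gene counts in microglia of 1086 with it and 2623 without it. Its file header gives another version of the counting software (7.1.0) than the submitters' notes (2.1.1), and it lists 31053 genes against 27998 in the others. Counting of intron reads in that library alone would raise genes with the most intron sequence over those with the least, and this difference was at least 1.55 in each of 4 cell types, against at most 0.202 in the other 11 libraries. A larger share of nuclear RNA would raise Malat1, which has no intron, and its ratio less the median of genes with the least intron sequence was 0.38 at most (-0.42 at least), so nuclear RNA cannot be told apart from no such share. A biological difference of this library was not tested. Its mitochondrial share, depth and shallowest barcode (498 UMIs, against 1214 to 2464 in the others) leave cell quality open. They cannot be separated from the different counting that its header and gene list show.

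The second pattern is that astrocyte and oligodendrocyte transcripts were lower in microglia of aged than of young PDMCAO libraries, with medians of -2.11 and -1.86. With an estimated correlation the astrocyte list holds (adjusted p = 0.0204) and the oligodendrocyte list does not (0.0766). Free RNA or fragments of other cells, in proportion to those cells, would lower the same transcripts in unrelated cells. In endothelial cells the medians were -1.87 for astrocyte and -1.95 for oligodendrocyte transcripts, of which neither list holds with an estimated correlation (adjusted p = 0.0798 for each). Astrocytes and oligodendrocyte-lineage cells were 3.10% and 11.3% of cells in aged PDMCAO libraries and 5.14% and 34.3% in young ones, log2 ratios of -0.73 and -1.61. The astrocyte share thus differed by less than its transcripts did, but a share of cells and a level in CPM are unlike measures. Microglia were also deeper in aged than in young PDMCAO libraries (median 5932 against 3378 UMIs), which would lower the CPM of the same free RNA. In young microglia the medians after PDMCAO were 0.63 and 0.62, while the shares of astrocytes and oligodendrocyte-lineage cells went from 7.84% and 43.8% in sham to 5.14% and 34.3%, opposite to what free RNA in proportion to the cells would give. With shares that vary this much between libraries, free RNA and a change within microglia cannot be told apart. Uptake of myelin by microglia, which the age of the mice could change, was not tested.

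The third pattern is that interferon-response genes called in oligodendrocytes rise after PDMCAO. Free RNA of microglia or microglial fragments would give these genes the same ratio between the 2 cell types as homeostatic microglia genes. Their ratio of CPM in oligodendrocytes to CPM in microglia was 10.1 times that of homeostatic genes over all 8 libraries (SD of log2 ratios between libraries 1.16), against a bound of 5 set beforehand for excluding free RNA. Without female PDMCAO aged 2 it was 9.32 (SD 0.523), above 5 by more than the spread. These 7 genes were chosen by their rise in oligodendrocytes, so a high ratio is expected of them and does not decide. The whole interferon list, which contains them, gave 6.82 (SD 0.971), and 5.20 (SD 0.531) without that library. The 24 genes of the list that were not called gave 3.86 (SD 0.823), and 3.53 (SD 0.566) without it, under 5 and above 3, the most allowed for free RNA beforehand. Against genes of disease-associated microglia the 7 genes had a ratio of 3.90. Free RNA from microglia and expression by oligodendrocytes therefore cannot be told apart for these 7 genes, and a response of oligodendrocytes to the surgery stays open. Without precursor clusters none of the 7 passed, while in cluster 0 alone, which is not a precursor cluster, Usp18 of the 7 passed. The lost calls thus do not show that the rise came from precursors.

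The surgery effect in microglia differed between ages by camera's test for 13 lists, and for 0 of them with an estimated correlation. The medians of aged minus young effects were -0.28 for disease-associated microglia, -0.14 for class II presentation, -0.41 for chemokines, -0.37 for lipid handling, -0.18 for oxidative phosphorylation and -0.33 for ribosomal proteins. They were 1.00 for cell cycle, 0.19 for immediate-early and stress genes, -2.79 for myelin, and, among transcripts of other types, -2.71 for oligodendrocytes, -2.35 for astrocytes, 2.64 for monocytes and neutrophils and -1.94 for neuronal, ependymal and choroid plexus cells.

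Other splits of the libraries show how often another grouping called as many genes. The limit was 0.05 of splits, without adjustment over the results tested. For surgery in microglia 1 of 50 splits gave as many genes, the real one with 1086. The others gave 405 at most, in a split with female PDMCAO aged 2 among the 4. For age after PDMCAO only the real split gave as many in microglia (1 of 35, 154 against 0) and oligodendrocytes (1 of 35, 81 against 65). These shares are under the limit, though 1 of 35 is the smallest these splits can give, and the 154 calls fell to 1 in the 8-group model. For sex (1 of 50, 5 against 0) the 5 genes lie on the sex chromosomes and follow the sex labels, so nothing follows about chance. For surgery in oligodendrocytes 2 of 50 splits gave as many, a share under 0.05, but the other of the 2 called 53 genes against 20. These 20 calls became 1, 0, 1 and 0 without male sham young 1, female sham young 1, male sham aged 1 and female sham aged 1, so the low share is weak evidence for surgery. Without female PDMCAO aged 2 the microglial values were 1 of 50 splits for surgery (2623 against 64) and 1 of 35 for age (968 against 333). Chance is not excluded for age in endothelial cells (2 of 35, 8 against 12) or astrocytes (4 of 35, 1 against 13). For surgery in these 2 cell types the real count is 0, so that 50 of 50 splits gave as many by construction and nothing follows about chance. The highest other splits for surgery called 431 genes in endothelial cells, 236 in astrocytes, 405 in microglia and 53 in oligodendrocytes, beside a median of 0 over the other splits in each. All 4 of these put female PDMCAO aged 2 among the 4 libraries set against 8, which points to a structure of the samples set by that library.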

How the results depend on the processing

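Most directions held under every setting, and calls of single genes depended on which libraries were in the fit. Ifi27l2a was higher in microglia after PDMCAO under every setting, with a log2 fold change across ages of 3.03 to 3.37 when each library was left out (edgeR, adjusted p = 0.000162 to 0.0137). Over genes open to naming, also unnamed or uncalled ones, and each left-out library, 8712 values kept threshold side and direction, 1159 fell short, 188 passed and 13 turned. With an estimated correlation 165 of 369 list results were no longer past the test, and with fry 141. Genes changed 4-fold in a simulation with these 12 libraries were called in 81% of cases in microglia for PDMCAO minus sham and 39% for age in sham, and genes changed 2-fold in 28% and 3%. Simulated without female PDMCAO aged 2, these were 93% and 74% for 4-fold and 80% and 35% for 2-fold changes. With 2 sham libraries at each age and 7 residual degrees of freedom, uncalled genes are not shown to be unchanged. Lists without female PDMCAO aged 2, list settings in cell types other than microglia, other limits for mixed clusters, and edgeR on cell counts were chosen after seeing the data. So was the limit of 0.11 in use, as were the settings without precursor clusters and with the largest cluster only in oligodendrocytes.

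Where a setting is named below, counts of genes past the threshold are given in a fixed order where all apply. The order is microglia (PDMCAO minus sham across ages, young, aged, then aged minus young in sham and after PDMCAO, interaction, sex), then endothelial cells, astrocytes and oligodendrocytes (PDMCAO minus sham, then aged minus young after PDMCAO). Without a filter on low counts they were 1746, 530, 1637, 129, 1725, 340 and 509 in microglia, 78 and 662, 6 and 307, and 34 and 180, and Ifi27l2a passed for age in sham (1.92, adjusted p = 6.3e-08) and after PDMCAO (1.61, adjusted p = 8.4e-15). With only the libraries numbered 1 they were 2270, 942, 1733, 102, 443, 18 and 11 in microglia, 28 and 36, 42 and 18, and 359 and 170. That setting leaves out female PDMCAO aged 2. Ifi27l2a then passed for age in sham (1.93, adjusted p = 3.0e-05) and after PDMCAO (1.83, adjusted p = 6.3e-06). For the causes of the changes below, unless stated, the cause was not tested.

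In DESeq2 the counts were 359 (young), 37 (age, sham), 471 (age, PDMCAO) and 16 (interaction) in microglia, 5 and 79 in endothelial cells, 2 and 33 in astrocytes, and 117 and 495 in oligodendrocytes, with Ifi27l2a for age after PDMCAO at 1.58 (adjusted p = 0.00165). With RLE normalization the count for age in sham microglia was 0. The 8-group model gave 644, 100, 183, 0 and 1 for the first 5 microglial comparisons, with Ifi27l2a at 3.39 in young (adjusted p = 0.0651) and 3.04 in aged mice (adjusted p = 0.0546) and -0.0551 between the sexes. With only the groups compared in the fit the counts were 835 (young), 16 (aged), 399 (age, sham) and 1 (age, PDMCAO), and Ifi27l2a was 3.34 in young mice (adjusted p = 0.165) and 1.93 for age in sham (edgeR, adjusted p = 5.1e-21). For age in sham that fit left almost no freedom to estimate the spread, so its calls and p do not measure spread between libraries. Thinned to the smallest library they were 0 (age, sham) and 23 (age, PDMCAO). With no doublets removed the counts were 5 (age, sham microglia), 5 (age, PDMCAO endothelial cells) and 5 (surgery, oligodendrocytes). The stricter cell filter gave 21 (age, endothelial) and 5 (surgery, oligodendrocytes), and Leiden resolution 2 gave 3 (age, astrocytes) and 10 (surgery, oligodendrocytes). With mixed clusters left unnamed from 0.2 the counts were 1 (age, sham microglia) and 13 (surgery, oligodendrocytes), where H2-T23, H2-K1 and H2-D1 no longer passed. From 0.1 each gene count was as with 0.11, and T and NK cells were 2.81 points higher after PDMCAO in place of 3.75 and 3.92 points higher in aged mice in place of 5.18, with 0 types past the test. In edgeR on cell counts 1 type passed for surgery and 1 for age. Without precursor clusters the counts in oligodendrocytes were 5 (surgery) and 117 (age), and with the largest cluster only, which had 15 cells in female PDMCAO aged 2, they were 23 and 32. In that cluster Cxcl14 turned direction for surgery (-0.24), and Rtp4 (-1.20), Cxcl14 (-0.86) and Fau (0.0170) for age, with none of the 4 values past the threshold.

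When each library was left out, the microglial counts were 413 to 2623 (surgery, both ages), 11 to 1007 (young), 1 to 1932 (aged), 0 to 46 (age, sham), 1 to 968 (age, PDMCAO), 0 to 1 (interaction) and 5 to 13 (sex). They were 0 to 28 and 1 to 97 in endothelial cells, 0 to 14 and 0 to 22 in astrocytes, and 0 to 199 and 19 to 406 in oligodendrocytes, and 0 cell types passed by share. Where this left a group with 1 library, that library was assumed to vary like the other groups. With a library left out, few exact permutations remain (27 or 54 for surgery, 72 for age). A type could then pass by share only if several types reached the smallest p, so that 0 does not show unchanged shares. Ifi27l2a was 3.02 to 3.71 in young mice (adjusted p up to 0.265), 2.86 to 3.30 in aged mice (up to 0.227), 1.68 to 2.21 for age in sham, 1.25 to 1.94 for age after PDMCAO, -0.68 to 0.0127 for the interaction and -0.19 to 0.23 between the sexes (edgeR). The share of microglia with an Ifi27l2a UMI was 19.1 to 27.3 points higher after PDMCAO and 15.1 to 20.3 points higher in aged mice. With only libraries numbered 1 it was 23.3 and 16.5 points higher, with an exact permutation p = 0.125 for each, the smallest possible with so few libraries.

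Genes that turned direction when some library was left out were not past the threshold there, and their ranges over all left-out libraries were as follows. In astrocytes they were Gfap (-0.0666 to 0.72) and Hba-a2 (-3.11 to 0.0127) for surgery and Pcna (-0.79 to 0.11) for age. In endothelial cells they were, for surgery, Aldoc (-1.21 to 0.27), Ly6c2 (-0.0759 to 1.88) and Ms4a7 (-0.68 to 1.43). In microglia they were Rarres2 (-2.28 to 0.64) in aged mice, Ermn (-0.10 to 1.97) for age in sham and, for the interaction, Mki67 (-3.89 to 5.07), Tk1 (-0.39 to 3.32), Ly6c2 (-1.49 to 8.64) and Plac8 (-2.52 to 4.22). With only libraries numbered 1, Ifi27l2a between the sexes was -0.28, Rpl11 (0.0658), Rps16 (0.0568) and Rps26 (0.0220) turned for age in endothelial cells, and Gfap (-0.0493, surgery) and Nfkb1 (-0.23, age) in astrocytes.

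Several lists turned direction too. Without female PDMCAO aged 2 they were lysosome for age in endothelial cells (adjusted p in the new direction = 3.7e-05), astrocytes (0.000256) and oligodendrocytes (2.1e-06), and ribosomal proteins for age in endothelial cells (0.327) and for surgery in astrocytes (9.7e-05). In microglia they were oxidative phosphorylation for the interaction (adjusted p = 0.898), and for sex chemokines (0.0229), oxidative phosphorylation (0.0236) and monocyte and neutrophil transcripts (0.00589). With only libraries numbered 1 they were, for age, lysosome in endothelial cells (adjusted p = 5.1e-11), astrocytes (8.6e-09) and oligodendrocytes (8.3e-12), ribosomal proteins in the same types (0.00236, 0.933 and 0.0928), homeostatic genes in endothelial cells (0.191) and astrocytes (0.828), and class II presentation in astrocytes (0.00241). For surgery they were homeostatic genes in endothelial cells (adjusted p = 0.00574) and oligodendrocytes (0.00137) and angiogenesis in endothelial cells (0.196). In microglia they were oxidative phosphorylation for the interaction (adjusted p = 0.225), and for sex interferon response (0.0416), blood-brain barrier (0.0330) and transcripts of oligodendrocytes (0.950), endothelial cells (0.0313) and monocytes and neutrophils (0.0151).

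Cell type shares that turned direction did so at differences far from the threshold. With only libraries numbered 1 they were endothelial (-3.42 points), ependymal (-0.180), pericyte (-0.0578) and smooth muscle cells (-0.175) for surgery, and choroid plexus (2.101), endothelial (-5.26) and fibroblast (0.0387) for age. The ranges over left-out libraries were, for surgery, endothelial -0.492 to 5.54, ependymal -0.553 to 0.428, pericyte -0.101 to 0.284, red blood cell -0.900 to 0.0585 and smooth muscle -0.143 to 0.144 points, and for age choroid plexus -1.60 to 0.756, endothelial -3.75 to 3.41, fibroblast -0.218 to 0.0406 and red blood cell -0.131 to 0.552 points. Others were choroid plexus for age with the stricter filter (0.622) and among non-microglial cells (0.0612), and border macrophages for age at Leiden resolution 2 (-0.00478). On the log odds scale they were smooth muscle for surgery (-0.169) and endothelial (-0.0663) and fibroblast for age (0.0636), and in edgeR on cell counts ependymal for surgery (-0.45) and endothelial for age (-0.29).

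The labels give sham and PDMCAO libraries the replicate number 1 and the PDMCAO groups also 2, without saying that a number pairs libraries. Same-numbered libraries did not deviate together, with 6 correlations of -0.0711 to 0.0987, of which 0 were over 0.1. With the replicate block the counts were 722 (surgery, both ages), 357 (aged) and 83 (age, PDMCAO) in microglia and 1 and 15 in endothelial cells. With the block Gfap in astrocytes for surgery was -0.18 (edgeR, adjusted p = 1.00), homeostatic genes in oligodendrocytes turned direction (adjusted p = 0.0230), and shares for surgery were -3.42 (endothelial), -0.180 (ependymal), -0.0578 (pericyte) and -0.175 points (smooth muscle).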

Other observations

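The values in this part were chosen after they were seen, and no test was run on them beyond those named. UMIs of Ifi27l2a were also counted in other immune cells, here as CPM without TMM scaling, and RNA from other cells in their droplets was not separated from their own. Border macrophages had 482 ± 240.3 in young sham, 781 ± 170.03 in aged sham, 489 ± 342 in young PDMCAO and 622 ± 29.2 in aged PDMCAO libraries (SD, n = 2, 2, 4 and 4). Dendritic cells of aged PDMCAO libraries had 1184 ± 127 over 165 cells (n = 4). There pericytes had 549 ± 685, fibroblasts 512 ± 408 and other non-immune types 37.1 (astrocytes) to 329 (oligodendrocytes). Thus not only immune cells were high.

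In aged sham microglia Cxcl13 had 80 UMIs and Serpina3n 12, against 0 for each in young sham microglia, which makes them at least 19.0-fold and 2.85-fold higher against a floor of 3 counts. The cell cycle inhibitor gene Cdkn2a was 11.6 ± 4.03 CPM (TMM) in aged and 2.64 ± 2.61 in young PDMCAO microglia (SD, n = 4 and 4) and missed the threshold (edgeR, log2 fold change 2.24 ± 0.60, adjusted p = 0.103).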
